A study of Homo sapiens with 6 samples.

How the data were processed

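Chromatin contacts were measured by Micro-C in HAP1, a near-haploid human cell line derived from the chronic myeloid leukaemia line KBM-7 that grows attached to the dish. Micro-C is a form of Hi-C in which micrococcal nuclease cuts chromatin down to nucleosomes before ligation, so that contacts are resolved more finely than with restriction enzymes. Per the labels' protocols, diploid HAP1 cells were sorted by their DNA stain, fixed with 1% formaldehyde for 10 min and then with 3 mM DSG (a longer protein crosslinker) for 45 min. Nuclease digestion was set to leave 80 to 90% of fragments as monomers. The labels describe 6 replicates in 1 group; nothing in them says whether these were separate cultures.

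The data used here are 1 list of chromatin loops for the whole series, in which the replicates are not told apart. Each row is a loop, that is, a pair of anchors on the same chromosome whose contact count exceeds that of the surroundings. The submitters' processing notes name BWA and the hg19 build, without saying which step used them. The file header names juicer_tools version 1.22.01, and its column names are those of the HiCCUPS loop caller. How the libraries were pooled, their sequencing depths and the caller's settings are not given in the sources used here. The authors deposited, for each loop, the observed contact count of the pixel where its anchors cross, as whole raw counts. They also deposited 4 expected values on the same count scale, which the caller computes from the lower-left, donut, horizontal and vertical surroundings of the pixel. The deposited q-values (p-values adjusted by the caller) give the significance against each surrounding. The authors' file also gives the count of significant pixels merged into the loop and the radius of that cluster in bp, a unit of its own.

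The values in the file show what it was filtered on. The smallest ratio of observed to expected was 1.75 for the donut and for the lower-left surroundings and 1.50 for the horizontal and vertical ones. For loops of a single pixel the 4 q-values summed to at most 0.0199, whereas loops of several merged pixels had single q-values as high as 0.797. Of all loops, 72.0% had each of the 4 q-values at or below 0.1. The list held 0 duplicate loops. Coordinates were read as hg19, the build named in the processing notes, and are printed 1-based. On 13 chromosomes the last loop lay beyond the last gene of the GRCh38 table at hand, by up to 2.35 Mb. A loop can lie beyond the last gene, so this does not tell the builds apart. The GRCh38 table holds no hg19 positions, and no hg19 genome or annotation was used here. The planned tests of promoter anchors, of 10 gene lists and of CTCF motif orientation were therefore not run, and loops are named by position, not by gene.

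Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Loop strength was the observed count over the donut expectation, and span the distance between anchor midpoints. Loops per chromosome were compared with an even spread over the covered length (first to last loop) by a Monte Carlo chi-square test of 100000 draws. Each chromosome was then tested with an exact binomial test, two-sided, with Benjamini-Hochberg adjustment. Since loops cluster, a 95% interval from 1000 resamplings of 5 Mb blocks is given beside each ratio. Differences in median span and rank correlations across loops were tested with 100000 permutations, two-sided. Anchors that overlapped by at least 1 bp were merged. Sharing of anchors was compared with 1000 draws in which every loop was moved by 200 kb to 1 Mb with its span kept (one-sided Monte Carlo p). Loops are not independent replicates, so these p-values describe the list and not the spread between cultures.

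Contact depth along chromosomes was added after the data had been seen. It is the log2 of the donut expectation of a 5 kb loop minus the median of loops of like span (40 span bins), summarised as medians of 1 Mb windows with at least 3 loops. Windows were split into stretches by binary segmentation, with at least 10 windows a stretch and a standardised difference of at least 8. That limit was chosen after 10 settings had been tried (limits of 6, 8 and 10 on the donut, lower-left and observed values of 5 kb loops, and 8 on 10 kb loops). The rule for neighbouring long loops (both anchors within 200 kb, sums within 10 kb) was likewise set while the data were explored. Intervals for steps come from resampling runs of 5 windows. They hold the ends of a stretch fixed, although the segmentation had chosen those ends on the same values.

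The functions were tested on simulated data. With 46849 evenly spread loops, 0.04 of 23 chromosomes were called on average, and chromosomes given 1.5 times the loops were called in 100% of cases. Those loops were drawn independently, so the rate of false calls among clustered loops was not tested. Loops placed at random anywhere on their chromosome gave a sharing ratio of 1.01 against draws placed in the same way. The local shifts used for the main comparison were not simulated. The segmentation split 2 of 105 simulated chromosomes without a step. It placed 47 of 50 planted steps of 1 log2 unit over 26 windows within 3 windows at both ends. Whether the simulated chromosomes vary in depth over long distances as real ones do was not tested, so false splits may be more frequent in the real data. No smaller and longer step was planted, so the simulations do not cover the step of 0.38 over 92 windows on chromosome 1.

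The loops named were fixed by a rule before the data were examined. These are the 10 strongest loops among those with an observed count above the median, the 5 longest loops and the 10 anchors with the most loops. Alternatives were a stricter q-value limit (each of the 4 at or below 0.1 times its largest value in the list), loops of 2 or more merged pixels, single anchor widths, other expected values, other definitions of a shared anchor and other random placements. With 1 pooled list there was no comparison between groups and no replicate could be left out. Exact Poisson and exact binomial (Clopper-Pearson) 95% intervals cover counting error only.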

Results

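The Micro-C data describe the three-dimensional contacts of wild-type HAP1 cells, in a series that set out to link regulatory elements to the genes they act on. The 6 replicates form 1 group, and the loop list made from them held 46849 loops on 23 chromosomes. None joined different chromosomes. Anchors were 5 kb wide for 39722 loops (84.8%, exact 95% interval 84.5 to 85.1%) and 10 kb wide for 7127. The depth behind a loop was a median of 31 observed contacts (quartiles 21 and 48, range 8 to 1756). A count of 31 has an exact Poisson 95% interval of 21.1 to 44.0, and the smallest count, 8, one of 3.45 to 15.8. Single loops are thus known far less precisely than the medians over many loops. A median of 3 significant pixels had been merged into a loop, and 4190 loops (8.94%) rested on a single pixel.

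Loops were spread unevenly over the chromosomes. Chromosome 19, the most gene-dense human chromosome, carried 25.3 loops per covered Mb against 16.0 genome-wide, a ratio of 1.58 (95% block interval 1.17 to 1.96). Chromosome 15 followed the same direction with 19.4 loops per Mb (ratio 1.21, interval 1.02 to 1.42), as did chromosome 12 with 18.4 (ratio 1.15, interval 1.02 to 1.27). At the other end, chromosome 21 carried 11.4 loops per Mb (ratio 0.713, interval 0.468 to 0.941) and X carried 12.8 (ratio 0.802, interval 0.675 to 0.928). Contact depth also differed between these chromosomes. The median depth ratio of their 5 kb loops was 1.33 on chromosome 15, 1.02 on 12, 0.864 on 19, 0.913 on 21 and 0.876 on X.

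The departure from an even spread was larger than counting error (chi-square 984, Monte Carlo p = 1e-05, the smallest that 100000 draws can give). By exact binomial tests, 9 chromosomes were above and 12 below the even value after adjustment, and chromosomes 11 and 20 were not called. Once loops were resampled in 5 Mb blocks, the interval excluded 1 for 3 of the higher and 2 of the lower chromosomes, those named above. The 23 block intervals are not adjusted for their number, and those of chromosomes 12 and 15 barely exclude 1. Covered length also counts long stretches without anchors, so a low ratio need not mean few loops in the rest of a chromosome. Chromosome 9, called lower (ratio 0.838), holds such a stretch of 32.5 Mb. With the number of 1 Mb windows that hold an anchor as the length, 7 chromosomes were above and 11 below. With 10 kb loops alone, chromosome 21 had a ratio of 1.03 (adjusted p = 0.852, exact binomial test) and X one of 0.919 (adjusted p = 0.222). Without its stretch of higher contact counts, described below, chromosome 15 had a ratio of 1.01 (adjusted p = 0.876, exact binomial test).

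**Figure D1:**
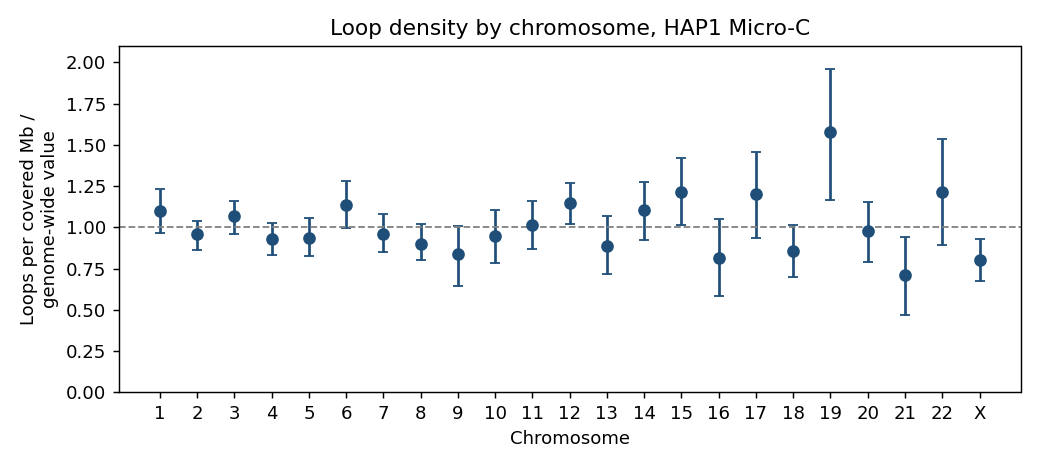
Loops per covered Mb of each chromosome divided by the genome-wide value (y axis, ratio) by chromosome (x axis); points are ratios and bars 95% intervals from resampling 5 Mb blocks. Chromosome 19 stands highest at 1.58 and chromosome 21 lowest at 0.713; the dashed line marks an even spread.

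Most loops were short. The median span was 160 kb (95% interval 155 to 160 kb, quartiles 70 and 360 kb), and the range ran from 35 kb to 8.305 Mb. Loops under 100 kb made up 36.3% of the list (17021 loops), those of 100 to 200 kb 19.8%, those of 200 to 500 kb 27.7%, those of 500 kb to 1 Mb 12.3% and those above 1 Mb 3.83% (1796 loops). Loops called with 10 kb anchors spanned a median of 370 kb and those with 5 kb anchors 130 kb. The difference of 240 kb was far beyond what reassigning the widths among loops gave (permutation p = 1e-05, the smallest possible with 100000 resamples). Span is set in part by the resolution of the call: the shortest loops were 35 kb with 5 kb anchors and 50 kb with 10 kb anchors. Part of the difference is therefore built in, and the p-value does not show that the loops differ in kind. By chromosome the median span was longest on chromosome 15 (205 kb) and shortest on chromosome 19 (120 kb), with 125 kb on chromosome 17. Chromosome 15 holds the stretch of higher contact depth described below, and its median span without that stretch was not computed.

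Longer loops had higher ratios of observed to expected contacts, along with lower expectations. The median ratio of observed to expected contacts was 2.63 for loops under 100 kb, 3.79 at 100 to 200 kb, 4.49 at 200 to 500 kb, 5.13 at 500 kb to 1 Mb and 6.33 above 1 Mb. Over all loops it was 3.55 (quartiles 2.59 and 5.41). Both anchor widths showed the rise: from 2.65 to 8.48 between the shortest and longest class for 5 kb anchors, and from 2.17 to 4.32 for 10 kb anchors. Across loops, span and strength correlated with Spearman's rho = 0.53 and Pearson's r = 0.50 on log2 values (permutation p = 1e-05 for each, the smallest possible). Without the 2 loops farthest from the median span, rho was again 0.53, but 2 of 46849 loops can hardly move a rank correlation.

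Contact counts themselves fell with span over these classes. The observed median went from 40 contacts under 100 kb to 17 above 1 Mb, and the donut expectation from 14.5 to 2.66. Over all loops, rho between span and strength fell from 0.53 to a median of 0.21 within 50 bins of like expectation (lowest -0.15, above 0 in 48 bins). Among 5 kb loops it was 0.69 in all and had a median of 0.45 within 50 bins of like expectation, in every one of which it was above 0. Among 10 kb loops the values were 0.63 and 0.18, and 48 of the 50 bins were above 0. Span and expectation were themselves correlated (rho = -0.72 over all loops), so such bins also narrow the range of spans and cannot separate these effects. The list holds no loop with fewer than 8 contacts, so a low expectation by itself sets a high least ratio. At the median expectation, 8 contacts give a ratio of 2.07 at 500 kb to 1 Mb and 2.86 at 1 to 2 Mb. How much of the relation comes from this selection was not tested.

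**Figure D2:**
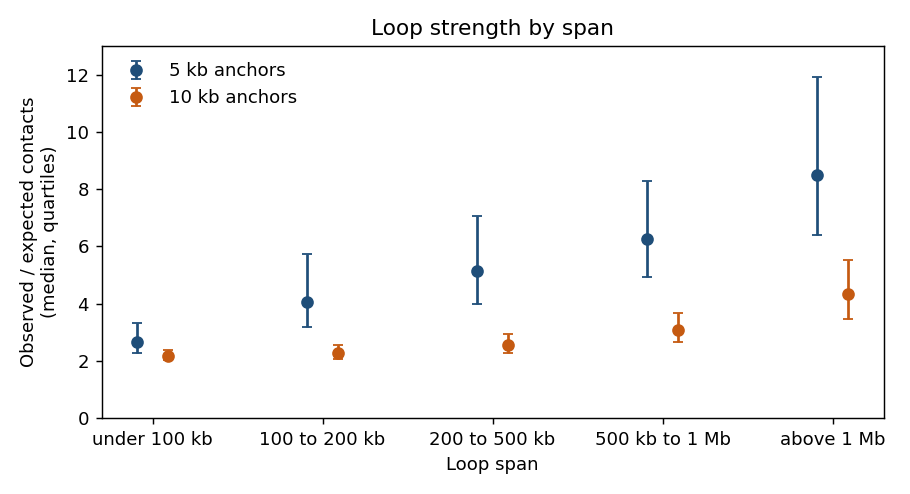
Observed over expected contacts (y axis, ratio) by span class (x axis) for loops with 5 kb and 10 kb anchors; points are medians and bars the quartiles across loops. The median rises from 2.65 to 8.48 for 5 kb anchors and from 2.17 to 4.32 for 10 kb anchors.

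The same anchors were used again and again. After merging, the list had 47497 anchors, and 45.9% of them held at least 2 loops. Of all loops, 89.7% shared an anchor with another loop, against 38.7% ± 0.272 (SD over 1000 draws) when loops were moved locally, a ratio of 2.32. An anchor was the lower end of one loop and the upper end of another in 20.3% of cases, against 6.17% ± 0.0820 in the draws. That share is taken over all anchors, of which only 11.8% held at least 2 loops in the draws. It therefore does not show that loops at a shared anchor run both ways more often than in the draws. In all, 3189 anchors held 5 or more loops, where the local shifts gave 13.3 on average, and 79 held 10 or more. For each of these shares no draw reached the observed value (n = 1000 draws, one-sided Monte Carlo p = 0.000999, the smallest possible). The contrast depends on how near anchors must be: when anchors within 10 kb of each other counted as the same, 96.8% of loops shared one against 91.0% in the draws, a ratio of 1.06. The draws do not account for bins in which reads map poorly.

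**Figure D3:**
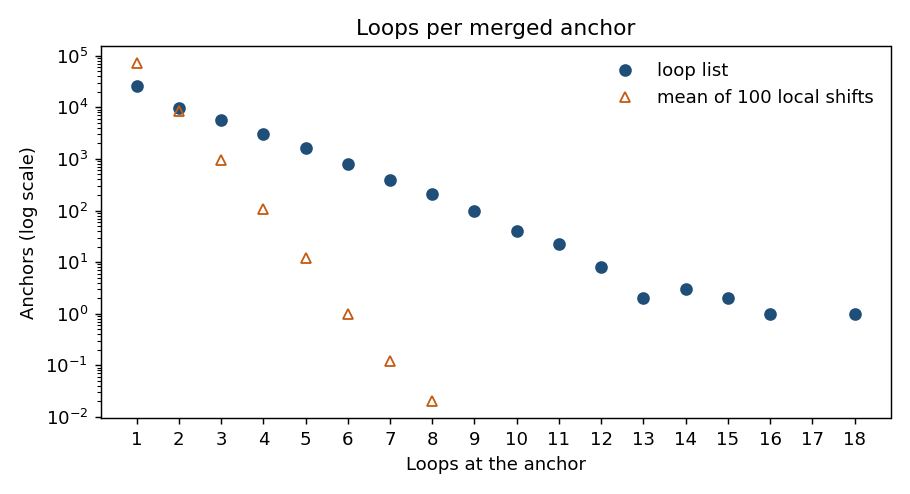
Number of merged anchors (y axis, log scale) by the number of loops each holds (x axis, loops); filled points are the loop list and triangles the mean of 100 sets of locally shifted loops. Anchors with 5 or more loops number 3189 in the list and 13.3 on average in the shifted sets.

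The anchor with the most loops lay on chromosome 6 (hg19, 27860001 to 27870000). It held 18 loops, 15 of them to lower coordinates, with spans from 55 kb to 1830 kb. The next, on chromosome X (130960001 to 130970000), held 16 loops that all ran to higher coordinates, up to 2090 kb away. Another one-sided anchor, on chromosome 3 (187450001 to 187460000), sent its 12 loops to higher coordinates with ratios of observed to expected of up to 23.7, and had the highest median ratio of the 10 anchors. Chromosome 6 at 139690001 to 139700000 (13 of 14 loops to higher coordinates), chromosome 7 at 70160001 to 70170000 (13 of 14 to lower) and chromosome 3 at 71630001 to 71640000 (12 of 13 to lower) were nearly one-sided.

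Loops ran more evenly both ways from the anchor on chromosome 5 at 124070001 to 124080000, with 7 of 14 to each side. Chromosome 15 at 75740001 to 75750000, inside the stretch of higher contact depth described below, held 15 loops, 9 of them to lower coordinates. On chromosome 2, the anchor at 222430001 to 222440000 held 15 loops (12 to lower coordinates) and that at 206540001 to 206550000 held 13 (10 to lower). Each of the 10 merged anchors was 10 kb wide, so that each can take in both 5 kb and 10 kb calls. Which genes lie there was not analysed here.

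The 10 strongest loops were not typical ones. Their observed counts were 36 to 111, but the donut expectation was only 0.0204 to 0.154 contacts, and they spanned 1.30 to 7.92 Mb on 8 chromosomes. The highest ratios, 2015 and 2008, belonged to a pair of loops on chromosome 19. These joined 23475001 to 23480000 with 28300001 to 28305000 (41 contacts), and 23630001 to 23635000 with 28305001 to 28310000 (49 contacts). A loop on chromosome 5 between 170260001 to 170265000 and 178180001 to 178185000 had 86 contacts (ratio 1825). On chromosome 11, 48745001 to 48750000 and 54890001 to 54895000 were joined by 65 contacts (ratio 1396). On chromosome 15, 75620001 to 75625000 and 78240001 to 78245000 had 111 contacts (ratio 1214), inside the stretch of higher contact depth described below. The remaining 5 lay on chromosomes 10, 17 (a pair), 4 and 9, with ratios from 630.1 to 1061. Of the 10, 4 bridged an anchor-free stretch of at least 3 Mb (described below), which is thus part of their span in hg19: the pair on chromosome 19 and the loops on chromosomes 11 and 10. With an expectation this small the ratio has little precision, and the counts are the firmer measure.

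Strong loops with an expectation of at least 1 contact and a span under 2 Mb were also listed, a choice made after the values had been seen. The first joined chromosome 10 at 81295001 to 81300000 with 81980001 to 81985000 (101 observed contacts, 1.02 expected). The next joined chromosome 16 at 78565001 to 78570000 with 78790001 to 78795000 (101 observed, 1.14 expected). By count alone, also chosen afterwards, the highest was a 65 kb loop on chromosome 17 (41400001 to 41405000 with 41465001 to 41470000) with 1756 contacts against 66.0 expected. The third by count was a 990 kb loop on chromosome 12 (63265001 to 63270000 with 64255001 to 64260000) with 514 against 9.88. Of the 10 loops with the highest counts, 7 lay on chromosome 15, all of them between 65.0 and 84.2 Mb and so inside its stretch of higher contact depth described below. Of these 7, 2 had 10 kb anchors, whose pixels cover more of the map than those of 5 kb loops.

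The 5 longest loops spanned 6.40 to 8.305 Mb. The longest lay on chromosome 13, between 43440001 to 43445000 and 51745001 to 51750000, with 15 contacts in a single pixel. It was followed by the loop of 7.92 Mb on chromosome 5 already named. A loop of 7.46 Mb on chromosome 6 (153745001 to 153750000 with 161205001 to 161210000) had 141 contacts over 15 merged pixels, the best supported of these 5. The loops of 6.835 Mb on chromosome 4 (36 contacts) and of 6.40 Mb on chromosome 8 (11 contacts) rested on 1 pixel each. In the list as a whole, 231 loops spanned 2 Mb or more.

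Among loops above 2 Mb, groups of neighbouring loops lay along lines on which one anchor moved up as far as the other moved down. The clearest was on chromosome 7, where 7 loops joined 66510001 to 66730000 with 72015001 to 72245000, and the sum of their anchor positions varied by 15 kb only. Such constant sums (within 10 kb) held for 25 of 37 neighbouring pairs above 2 Mb (67.6%, exact 95% interval 50.2 to 82.0%). They held for 77 of 1350 pairs at 500 kb to 1 Mb (5.70%, interval 4.53 to 7.08%). The alignment had been noticed in these loops before it was counted, so no test of the difference is given. Pairs that share a loop are not independent, and the intervals are too narrow for that reason. The 25 pairs come from 17 loops in 5 groups, and without chromosome 7 the count was 5 of 14 (35.7%). The rule for pairs was set while the data were explored, and under 4 other rules the share above 2 Mb was 48.9 to 76.0%, against 2.08 to 13.4% at 500 kb to 1 Mb.

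**Figure D4:**
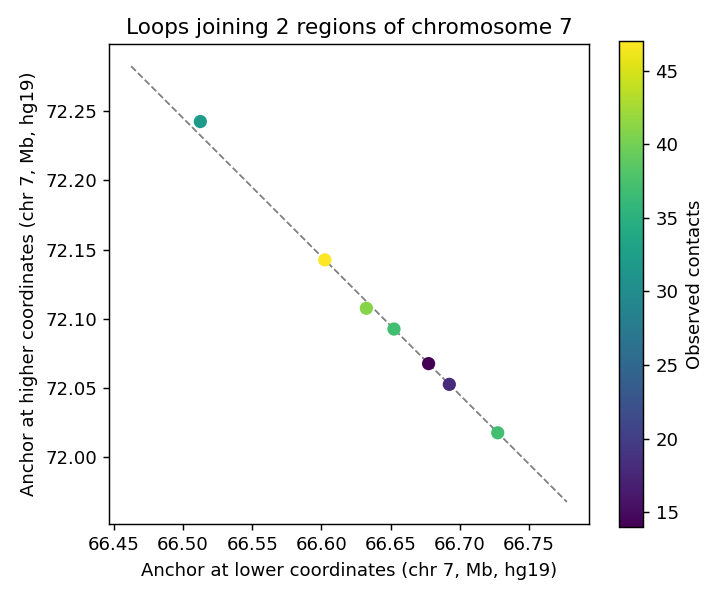
Midpoints of the lower (x axis, Mb) and higher (y axis, Mb) anchors of 7 loops on chromosome 7 in hg19 coordinates, coloured by observed contacts. The points follow the dashed line on which the sum of both positions is constant; the counts run from 14 to 47.

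Loop anchors were missing from long stretches of most chromosomes. In all, 19 stretches of at least 3 Mb held no anchor, each on a different chromosome, for 130.1 Mb together. The longest were on chromosome 9 (38710001 to 71195000, 32.5 Mb), chromosome 1 (121340001 to 142650000, 21.3 Mb) and chromosome 16 (33985001 to 46660000, 12.7 Mb). These are the chromosomes with the large heterochromatic blocks next to their centromeres. On X the longest stretch was 58060001 to 61745000 (3.69 Mb), followed by 90380001 to 93125000 (2.75 Mb). The first loops of chromosomes 13, 14, 15, 21 and 22, whose short arms are largely repetitive, began at 19.8, 20.8, 22.8, 10.8 and 17.1 Mb. Although no anchor lay inside them, 7 of the 19 stretches were bridged by 12 loops. These were the 12 loops on chromosomes 7, 10, 11, 12, 17, 19 and 20 with 13 to 69 contacts and expectations of at most 0.147, and 4 of them are among the 10 strongest loops. The list does not say whether reads, mappable bins or loops were missing there.

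Contact depth was not level along the chromosomes. On chromosome 15 the stretch from 62 to 88 Mb had 1.98 times the contact depth of the rest of the chromosome (95% interval 1.73 to 2.23). Its 26 windows of 1 Mb averaged 0.91 on the log2 scale (SD 0.25 between windows), and each lay above 0.3. The median observed count of 5 kb loops there was 50 against 32 elsewhere on the chromosome, and loops numbered 26.5 per Mb against 16.0. The ratio of observed to expected was much alike, 3.90 inside and 4.00 outside. On chromosome 1 the stretch from 145 to 239 Mb, beyond the long anchor-free stretch, had 1.30 times the depth of the rest (interval 1.17 to 1.41), and 39 contacts per 5 kb loop against 34. Its 92 windows averaged 0.33 (SD 0.40 between windows), and only 56 of them lay above 0.3. On the donut values the segmentation split no other chromosome at the limit used, which was chosen after 10 settings had been tried. At the same limit the lower-left values also split chromosome 13, and the observed counts split chromosome 15 alone. The stretch on chromosome 15 came back, with both ends within 3 Mb, in 8 of the 10 settings, and that on chromosome 1 in 3 of them. At the lowest limit up to 8 chromosomes were split, and with 10 kb loops none was. From 10 kb loops the log2 steps were 0.79 on chromosome 15 and 0.18 on chromosome 1, against 0.99 and 0.38 from 5 kb loops.

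**Figure D5:**
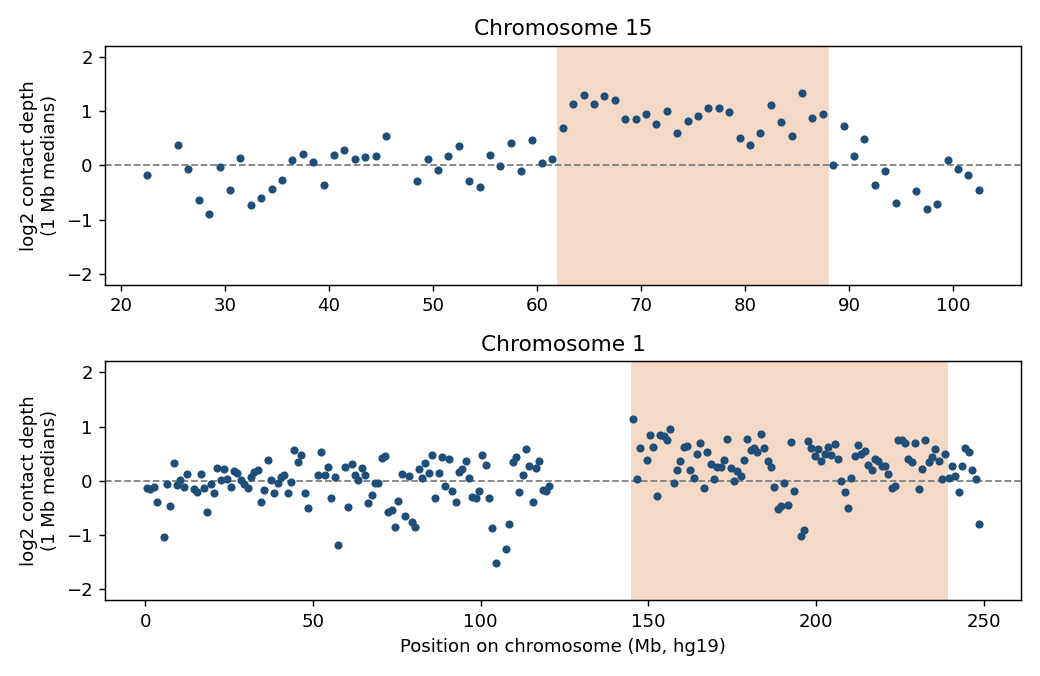
Contact depth of 5 kb loops in 1 Mb windows (y axis, log2 of expected contacts relative to loops of like span) along chromosomes 15 and 1 (x axis, Mb, hg19). Points are window medians and shading marks the stretches at 62 to 88 Mb and at 145 to 239 Mb, which averaged 0.91 and 0.33.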

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

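The alternatives without loops above 2 Mb, without the chromosome 15 stretch, with loops within 25 kb counted once, with loops placed anywhere and all those for contact depth were chosen after seeing the data. Of 69 alternative values computed, 25 concerned the main results, and 24 of these kept their direction and their side of the threshold or stayed within 1.5 times. Of the other 44 values, 33 kept their call or stayed within the interval of the value reported, 2 kept their direction without a call and 1 reversed. The remaining 8, which have no test, left that interval. Of these, 7 stayed within 1.5 times the value reported, and the other is the chromosome 1 step from 10 kb loops (0.18 against 0.38). The exception among the main results was the number of chromosomes that departed from an even spread, which was 21 in the full list and 8 (5 higher, 3 lower) with 10 kb loops alone. That set holds 7127 loops, so fewer loops were tested. Chromosome 21 then reversed from a ratio of 0.713 to 1.03, with no call, and the cause was not tested. The stricter q-value limit left 32542 loops, and requiring 2 merged pixels left 42659. Counting loops within 10 kb once removed none, so that setting tested nothing, though its values are among those counted above as kept. Counting loops within 25 kb once left 45362. The sharing ratio ran from 1.06 to 3.14 over its alternatives, against 2.32. The planned rotation of whole chromosomes keeps anchors shared and could not serve as a comparison, so each loop was placed anywhere on its chromosome instead (ratio 2.67). The correlation of span with strength ran from 0.47 to 0.69. The longest anchor-free stretch stayed at 32.5 Mb, and the number of 3 Mb or more went from 19 to 21 under the stricter limit. Tests of promoters, gene lists and CTCF motifs were not run for want of hg19 annotation, and with 1 pooled list neither leaving out a replicate nor a paired analysis was possible. Depth limits single loops: those above 1 Mb had a median of 17 contacts, though the 21 above 5 Mb had 31 (18 without the 2 that bridge an anchor-free stretch).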

Other observations

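All tests in this part, and their limits, were chosen after the data had been seen. Loops at a shared anchor tended to run the same way, and more so the longer they were. Of the 9936 anchors with exactly 2 loops, 67.3% (exact 95% interval 66.4 to 68.2%) sent both to the same side, where independent directions would give 50%. The span classes were then taken one at a time, counting anchors with exactly 2 loops of the class, whatever loops of other classes they held, so that an anchor can count in several classes. With spans at least 30 kb apart, the share was 61.6% under 100 kb (2095 anchors), 68.6% at 100 to 200 kb (1553), 81.0% at 200 to 500 kb (3769) and 87.4% at 500 kb to 2 Mb (1919). Among anchors with exactly 2 loops in the whole list, both in the class, the shares were 60.0% (826 anchors), 71.5% (263), 81.9% (730) and 90.9% (353).

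Without that distance rule, loops under 100 kb showed the opposite. Of 4283 anchors with exactly 2 loops of that class, 36.1% sent both to the same side, and of 1759 with exactly 2 loops in the whole list 33.7% did. Merging of neighbouring pixels by the caller, which removes pairs that end close together on the same side, is a candidate explanation. It was taken to predict a share of 50% once spans differ by 30 kb, and to be excluded by a share below 45%. The share was 61.6% (interval 59.5 to 63.7%), which is neither, so this explanation stays undecided. The deficit was gone at that distance, but the share above 50% has no account in it. For loops of 500 kb to 2 Mb, independent directions predict 50%, and the share with spans 30 kb apart was 87.4%. A further test, added after that value was seen, asked whether 1 broad contact split into several calls could account for it. That predicts a share near 50% with spans 100 kb apart, and the share was 87.3% (interval 85.5 to 89.0%). The hypothesis that anchors of long loops carry an orientation, as convergent CTCF sites would, stays open, since the motifs were not searched.

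The stretch of chromosome 15 at 62 to 88 Mb, with 1.98 times the contact depth, may be present in an extra copy. HAP1 cells are known to carry a segment of chromosome 15 inserted into chromosome 19. A copy added to each existing one predicts a step of 1 on the log2 scale, and the step was 0.99 (95% interval 0.79 to 1.16). Loop-dense chromatin with a higher contact yield was tested by removing the trend of depth on loops per window. This left a step of 0.75 (interval 0.54 to 0.89, with a limit of 0.4 for its lower bound). The fitted trend on called loops thus did not account for the whole step. Called loops per window are a noisy count, as low as 3, and that noise can flatten the fitted trend. That count can also itself rise with contact depth, and density measured otherwise was not tested. From observed counts the step was 0.79, just inside the lower end of the interval, and from 10 kb loops it was 0.79 as well but, before rounding, just outside. The stretch came back in 8 of the 10 segmentation settings tried. None of 1772 runs of 26 windows on other chromosomes (1 excepted) reached the mean of 0.91, and the highest was 0.13. The stretch had been chosen for its depth on these same values, so its mean and step can be too high. The comparison with other runs is a description and not a test. Where an extra copy would lie was not tested, because the list holds no contacts between chromosomes.

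The stretch of chromosome 1 at 145 to 239 Mb showed a smaller step of 0.38 (95% interval 0.23 to 0.49). An extra copy per 2 copies in all cells predicts 0.58, above that interval. After removing the density trend 0.31 was left (interval 0.20 to 0.38), so the fitted trend did not account for the whole step. The same weaknesses of the count of called loops apply here. The lower bound of that interval lies barely above the limit of 0.2, which is looser than the 0.4 used for chromosome 15. Under that limit the test would have been undecided. The stretch itself came back in 3 of the 10 segmentation settings tried, and its step was 0.18 from 10 kb loops, so its placement depends on the setting. None of 667 runs of 92 windows on other chromosomes with as many windows (15 excepted) reached its mean of 0.33, and the highest was -0.02. This stretch too had been chosen for its depth on the same values, so that comparison is no test. Its steps and their intervals can be too high for the same reason, which matters for a lower bound so near its limit. A gain in part of the cells or libraries may account for it and was not tested, because the replicates are pooled.

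The longest loops may mark sequence that is near-identical at both ends or ordered differently in these cells than in hg19, but no test here decides it. Loops above 5 Mb (21) had a median ratio of observed to expected of 165, those of 3 to 5 Mb (61) 13.7, those of 2 to 3 Mb (149) 7.34 and those of 1 to 2 Mb 6.06; with 1 added to both counts the values were 18.6, 8.08, 4.99 and 4.62. The value of 165 does not decide on ordinary loops, since at the median expectation of 0.172 above 5 Mb even the smallest count in the list, 8, gives a ratio of 46.5. That floor does not account for the observed counts, whose median was 31 above 5 Mb against 16 at 3 to 5 Mb, 15 at 2 to 3 Mb and 18 at 1 to 2 Mb. With 21 loops, however, the exact 95% interval of that median was 15 to 37, against 17 to 18 at 1 to 2 Mb, so the counts leave ordinary loops open as well. Of the 21, 2 bridge an anchor-free stretch of at least 3 Mb, and without them the median count was 18 and the median ratio 153. Of the 61 at 3 to 5 Mb 10 do, and without these the ratio was 10.1 and the count 15. The median ratio of loops of 2 to 3 Mb lay near the trend of shorter ones, so many of them can be ordinary. Their upper quartile was 14.6, however, against 8.84 at 1 to 2 Mb. An expectation under 1 was found for 20.8% of them, against 4.22%. Constant sums of anchor positions, which inverted copies or an inverted segment would give, were noticed in these loops before they were counted. They held for 67.6% of neighbouring pairs above 2 Mb, but for 5 of 14 (35.7%, exact 95% interval 12.8 to 64.9%) without chromosome 7, and these pairs take in 17 of 231 loops. Ordinary loops above 5 Mb and inverted or rearranged sequence thus both stay open.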
